A study of Mus musculus with 4 samples.

How the data were processed

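Small RNA was sequenced from mouse naive CD4+ T cells of the spleen, 2 samples transfected with ASO and 2 with CRO, activated for 48 h. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with the Illumina TruSeq small RNA kit. The submitters' processing notes name DESeq, with no version, and the mm9 genome build. The aligner, the miRNA annotation and any trimming are not given in the sources used here.

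The authors deposited 1 table of 1073 miRNAs and 1 count of differential miRNAs. Per the file headers, the table holds the authors' mean normalized signal over all libraries (base mean) and per group, a fold ratio, its log2, a p-value and an adjusted p-value. The fold and log2 columns of the deposited table are CRO over ASO, and were turned here to ASO over CRO. For 843 of 843 miRNAs with a finite ratio the deposited log2 value equals the reversed log2 of the group means. The authors' count table calls ASO the control and CRO the case, while the series text calls CRO the control.

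The design fixed before the data were examined assumed counts per library. Because the deposited columns are group means, the fallback written in that design was used, which takes the authors' p and adjusted p (threshold 0.05) as the result. Lists were compared by the percentile of their median log2 ratio among 10000 random lists of the same size matched on mean expression, among the 482 miRNAs with a base mean of at least 10. In simulated data a list of 12 shifted by 1 on the log2 scale reached the 100 percentile and an unshifted list the 29.8 percentile. The simulated miRNAs varied independently, and the shift was larger than the list medians reported below. Smaller shifts and correlated members were not covered.

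Counts per library were decoded from the group means. A mean of 2 libraries is a sum of 2 whole counts, each divided by its size factor, and the deposited values carry 15 significant digits. All 1073 miRNAs could be written in this way to within rounding, with a rounding tolerance set after the residuals were seen. 1 of them, miR-155-5p in ASO, could be written in more than 1 way, so its ASO counts are not given per library. Size factors recomputed from the decoded counts as median ratios, over 636 miRNAs above 0 in every library, matched all 4 decoded ones to a relative tolerance of 1e-09. They were 1.626 and 1.422 for ASO and 0.782 and 0.557 for CRO. On simulated group means the decoding recovered both counts of 100% of 1073 miRNAs in each group. Which decoded library is which replicate is not known.

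The 2 libraries of a group differed by more than sampling noise, with a chi-square over degrees of freedom of 230.1 in ASO and 498 in CRO. This test covers counting error only and does not show whether the libraries came from separate cultures. They were counted as separate samples because the labels list them so. The median absolute log2 ratio between them, over 273 miRNAs with a base mean of at least 100, was 0.23 in ASO and 0.39 in CRO. The PCR reads carry no molecular identifiers in the sources used here.

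The decoded libraries were fitted with limma 3.58.1 in R 4.3.3 (trend and robust options) on log2(normalized count + 1), as an alternative added after the files were seen. Folds on that scale understate the change of low miRNAs. In counts simulated for 482 miRNAs with 200 changed 4-fold and a dispersion of 0.05, limma recovered 96% and made 6 false calls. In the data it called 14 lower and 1 higher. A larger changed share eases the adjustment, so the simulated recovery does not carry over to the data. Lists were tested with camera at a correlation of 0.01, camera with an estimated correlation, and fry, with Benjamini-Hochberg adjustment over the 20 lists. In simulated data camera gave a p of 6.12e-17 for a list of 20 raised 2-fold and 0.486 for an unchanged one. The members of these lists were drawn independently. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the rest.

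The naming rule took the 10 largest decreases and the 10 largest increases past the authors' adjusted p with a base mean of at least 10 and groups that do not overlap. Where fewer increases passed, the smallest p filled the direction up to 5, said not to pass. It also took the 5 most counted miRNAs, 11 fixed ones, and the 2 members with the smallest p of each list called by camera.

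miRNA precursors of GENCODE M21 (GRCm38) were searched with BLAST 2.17.0 against that annotation's small non-coding and ribosomal transcripts, for matches of at least 25 bases at 95% identity. Precursor sequences were found for 475 of the 482 miRNAs. Because the authors used mm9, no coordinates are given, and host genes come from GRCm38. The alternatives were other pseudocounts (0.5 and 10), filters (none, and a base mean of at least 50), scalings (library totals and the upper quartile), limma-voom, leaving out each library, other thresholds on the authors' table, and leaving out the miR-297, miR-466, miR-467 and miR-669 names.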

Results

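Small RNA sequencing was used to ask how transfection with ASO, set against its control CRO, changed the miRNAs of activated T cells. Naive CD4+ T cells from mouse spleen were transfected with either agent, stimulated through CD3 and CD28, and collected after 48 h. Each group held 2 samples, and the labels do not expand the names ASO and CRO. The labels do not say that the samples of a group came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical. The deposited table listed 1073 mature miRNAs as group means. Counts per library were decoded from those means, which gave totals of 5617699 and 3300457 for the CRO libraries. The ASO totals lay between 9645524 and 10961808, because the counts of miR-155-5p could be split between the ASO libraries in 3 ways. The decoded libraries carry no replicate number and are called a and b.

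The same miRNAs dominated both groups. The 5 most counted, miR-155-5p, miR-16-5p, miR-21a-5p, miR-142a-3p and let-7f-5p, made up 52.3% of the summed authors' means in ASO and 49.6% in CRO. miR-155-5p, which is induced when T cells are activated, was the most counted, at 14.9% in ASO and 13.2% in CRO. In the authors' deposited table its mean was 1014550 in ASO and 865313 in CRO, a log2 ratio of 0.23 that did not pass (adjusted p = 1). None of the other 4 passed either, with log2 ratios from -0.06 for let-7f-5p to 0.35 for miR-142a-3p. Of the 482 miRNAs with a base mean (the mean over all libraries) of at least 10, 442 differed by less than 2-fold.

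Against this background 13 miRNAs passed an adjusted p of 0.05 in the authors' deposited table. Of these, 12 were lower in ASO and 1 was higher. The most counted of the 13 was miR-6240, with an authors' mean of 2821 in ASO and 22148 in CRO. Its log2 ratio was -2.97 (adjusted p = 0.0020, authors' deposited table). miR-6238 fell from 300.8 in CRO to 45.5 in ASO and had the smallest adjusted p of the authors' deposited table, 1.52e-07. miR-6239 fell from 166 to 24.2. Both arms of miR-712, which has been described as a product of ribosomal RNA precursors, were lower, with log2 ratios of -2.89 for miR-712-5p and -2.79 for miR-712-3p. The remaining largest decreases were those of miR-3470a (-2.66), miR-5126 (-2.48), miR-6538 (-2.20), miR-690 (-2.10) and miR-1949 (-2.05). miR-3068-3p (-1.73) and miR-7033-5p (-1.45) also passed but fell outside the naming rule, and were added after their values were seen. The other arm of the same precursor, miR-3068-5p, also chosen afterwards, had a log2 ratio of 0.25 (adjusted p = 1, authors' deposited table).

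The 1 miRNA that rose was miR-499-5p, whose gene lies within Myh7b, a myosin heavy chain gene. Its authors' mean was 49.1 in ASO and 6.79 in CRO, a log2 ratio of 2.85 (adjusted p = 0.015, authors' deposited table). The decoded counts were 75 and 74 in the ASO libraries and 5 and 4 in the CRO libraries. The 4 next increases by p did not pass in the authors' deposited table. These were miR-1983 (log2 ratio 1.20, adjusted p = 0.16), miR-96-5p (0.98, 0.33), miR-122-5p (1.39, 0.76) and miR-466h-5p (0.94, 0.93).

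**Figure D1:**
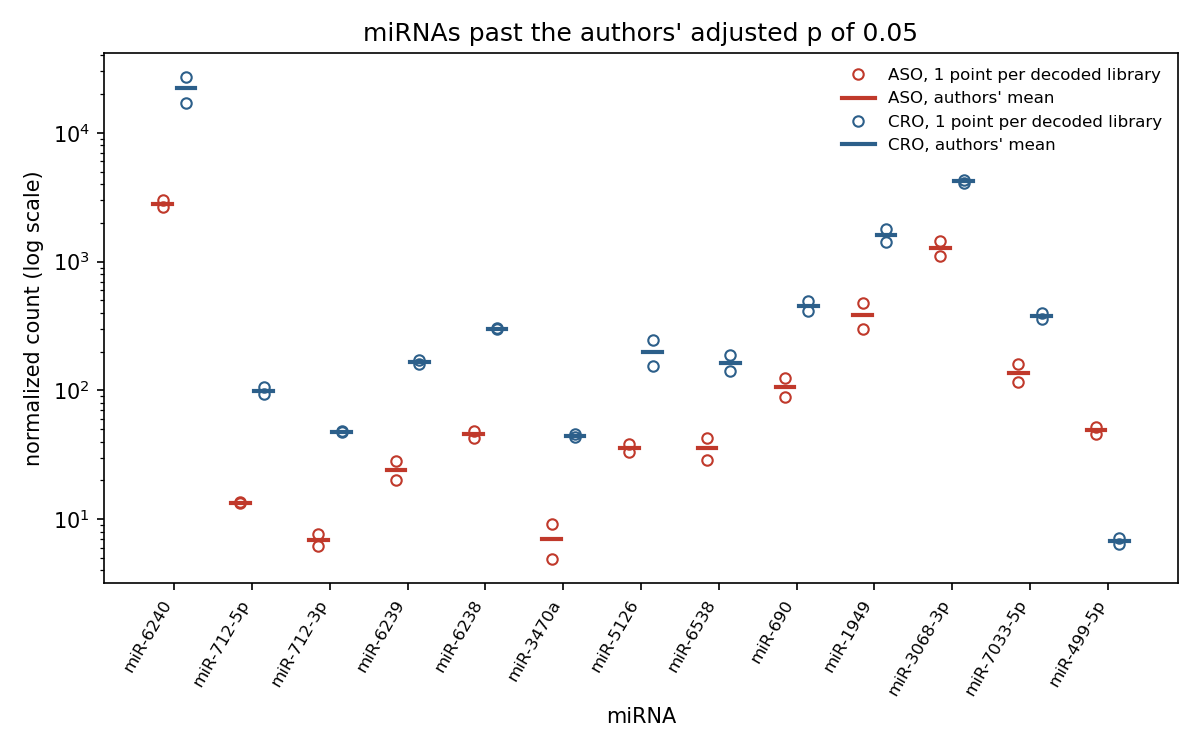
Normalized counts, on a log scale, of the 13 miRNAs past the authors' adjusted p of 0.05, with 1 open circle per decoded library and a bar at the authors' mean of each group. In 12 miRNAs both ASO libraries lie below both CRO libraries, and in miR-499-5p they lie above.

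**Figure D2:**
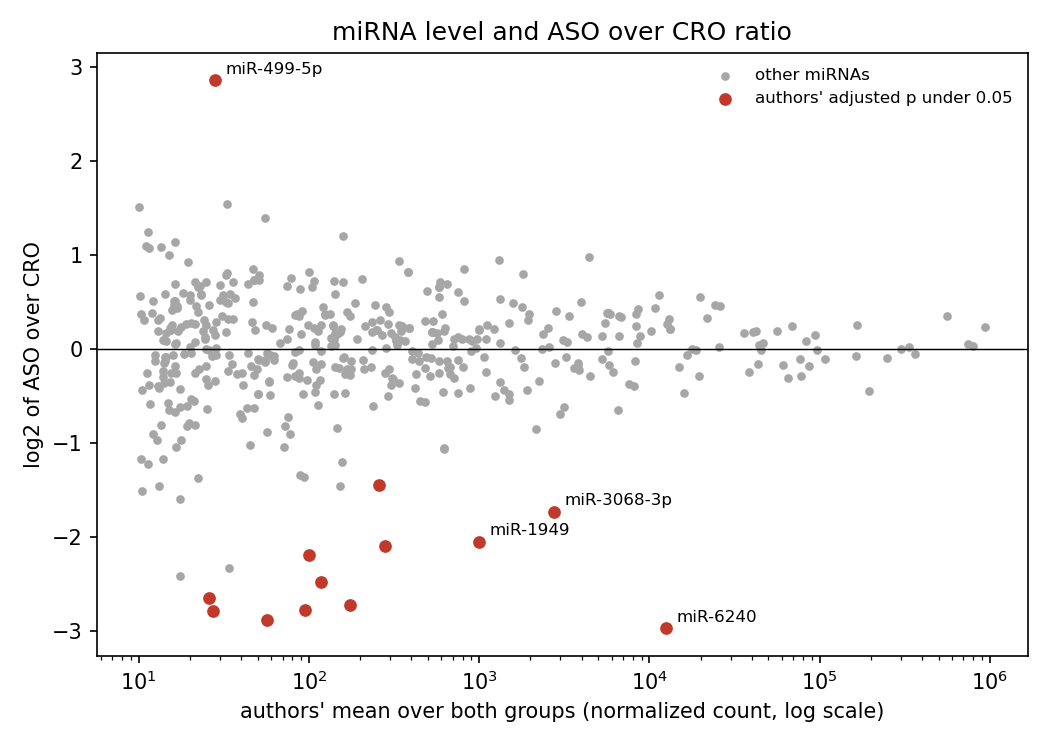
Log2 ratio of ASO over CRO against the authors' mean over both groups, on a log scale, for the 482 miRNAs with a base mean of at least 10. Red points passed the authors' adjusted p of 0.05, with miR-6240 at -2.97 and miR-499-5p at 2.85.

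In the decoded libraries both ASO values of the 12 lower miRNAs lay below both CRO values, which their choice by p largely fixes. Over all 482 tested miRNAs the groups did not overlap for 41.9%, against 33.3% by chance. A limma fit of these libraries, added after the files were seen, called 14 miRNAs lower and 1 higher at an adjusted p under 0.05, and included all 13 of the authors' calls. It gave a log2 ratio of -2.94 ± 0.27 (SE) for miR-6240, -2.70 ± 0.27 for miR-6238, -2.08 ± 0.30 for miR-1949 and 2.68 ± 0.39 for miR-499-5p. A fit without 1 library estimates variation only from the group that keeps both. The number of calls changed in such fits. It was 4 lower and 0 higher without ASO library a (31 at an unadjusted p under 0.05), and 10 and 0 without ASO library b (23 unadjusted). Without CRO library a the fit called 32 lower and 31 higher, and without CRO library b 23 lower and 8 higher. The lost calls kept their direction, which is fixed in advance where the groups do not overlap. Without ASO library a they were miR-6239 (log2 ratio -2.52), miR-712-3p (-2.48), miR-5126 (-2.31), miR-6538 (-1.90), miR-690 (-1.86), miR-1949 (-1.74), miR-7033-5p (-1.69), miR-3068-3p (-1.55) and miR-499-5p (2.77). Without ASO library b they were miR-3470a (-2.16), miR-7033-5p (-1.23) and miR-499-5p (2.60). Some named miRNAs passed only when a CRO library was left out, where the closer ASO pair alone sets the variation. miR-1983, miR-96-5p and miR-122-5p did so without either one, at log2 ratios of 0.90, 1.14 and 1.62 without CRO library a and 1.57, 0.83 and 1.13 without CRO library b. miR-466h-5p (1.17) and miR-486a-5p (-1.45) passed without CRO library a, and miR-466i-5p (-1.16) without CRO library b.

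The authors also deposited a count of differential miRNAs, which treats ASO as the reference. It gives 17 miRNAs higher in CRO and 4 lower in CRO, 21 in all. The same numbers came from the authors' deposited table with a raw p under 0.05 and at least a 2-fold difference, while 13 miRNAs passed the adjusted p.

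miRNAs with known roles in T cells did not pass in the authors' deposited table, each with an adjusted p of 1. Among those that activation induces, miR-21a-5p had a log2 ratio of 0.05 and miR-146a-5p, which restrains NF-kB signalling, -0.08. Among those that activation reduces, miR-150-5p had -0.45 and miR-181a-5p, which tunes T cell receptor sensitivity, -0.65. In the limma fit without CRO library a both passed (log2 ratio -0.83, adjusted p = 0.042, and -0.80, adjusted p = 0.029), and without CRO library b miR-150-5p was at 0.057. Single libraries also turned the sign of miR-21a-5p (-0.42 without CRO library b) and miR-146a-5p (0.10 without CRO library a), neither of which passed. Within the miR-17-92 cluster, miR-17-5p had 0.43 and miR-92a-3p -0.32. The values of let-7g-5p and miR-142a-5p were 0.14 and 0.00060.

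Groups of miRNAs were compared through 20 lists fixed before the data were examined. In 5 lists the median log2 ratio lay outside the central 95% of 10000 random lists matched on mean expression. That range was not adjusted for the number of lists. Random lists also do not carry the shared transcripts or shared reads that members of a list can have. None of the tested members of the 20 lists passed the authors' adjusted p, and the count adjusted over the list alone was also 0 in every list. The raw p was under 0.05 for 4 members of the Sfmbt2 list, and for 1 each of the activation-induced, miR-17-92 and epithelial lists. On the decoded libraries limma's camera with a preset correlation of 0.01 called 2 lists, and with an estimated correlation called none. The second form rests on the few degrees of freedom left by 2 libraries per group, so it could hardly call any list. For the erythroid list camera's p rose from 0.0037 to 0.097, although the estimated correlation was -0.25, below the preset one. The lack of calls therefore does not tell whether correlation among members accounts for the 2 calls.

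The Sfmbt2 intronic cluster, a large imprinted miRNA cluster, had 24 of 26 tested members with a ratio above 0. Its median was 0.45, at the 99.99 percentile of random lists, and camera gave an adjusted p of 0.00086. That call was lost with an estimated correlation (adjusted p = 0.82). Several members are near-identical copies whose reads cannot be told apart, and miR-669a-5p and miR-669p-5p have identical values. The 2 members with the smallest p were miR-466h-5p, with the ratio of 0.94 given above, and miR-466i-5p, at -1.05 (adjusted p = 1, authors' deposited table). The list was fixed by name, and the GRCm38 annotation places both arms of miR-466i, the 2 members below 0, outside Sfmbt2.

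Of the T helper and regulatory T cell list, 17 of 22 tested members had a ratio above 0. Its median was 0.24 (99.7 percentile), with miR-301a-3p at 0.94 and miR-10a-5p at -0.62, both chosen after their values were seen. The list reduced on T cell activation had 14 of 19 members below 0 and a median of -0.17 (0.40 percentile). Camera called neither list (adjusted p = 0.14 and 0.32). The first list came inside the random range without CRO library a, at a median of 0.31, and the second without CRO library b, at -0.12.

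Markers of other blood cells also lay below 0. All 5 tested erythroid markers had a ratio below 0, with a median of -0.67 (0.32 percentile) and a camera adjusted p of 0.037. Camera with an estimated correlation, which could hardly call any list, gave an adjusted p of 0.82. miR-451a had a log2 ratio of -0.50 and miR-486a-5p of -1.06, and each had an adjusted p of 1 in the authors' deposited table. All 4 tested myeloid markers lay below 0, with a median of -0.56 (1.76 percentile) and miR-223-3p at -0.25. Camera did not call the myeloid list (adjusted p = 0.14). It came inside the random range without ASO library b, CRO library a or CRO library b, at medians of -0.45, -0.51 and -0.37, and in the limma fits with no filter (-0.36) or a base mean of at least 50 (-0.48).

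The other 15 lists lay inside the random range in the authors' table. The list of the miR-17-92 cluster and its paralogues was near its edge, at the 95.4 percentile. In the limma fit of the decoded libraries it lay outside, with a median of 0.26 (98.6 percentile), as it did in 9 of 12 limma settings. It came inside the random range without ASO library b, CRO library a or CRO library b, at medians of 0.17, 0.44 and 0.16. Camera did not call it (adjusted p = 0.23). Leaving out a library moved 3 other lists outside. These were the list induced on T cell activation without ASO library a (median 0.37) or CRO library b (0.20), epithelial markers without ASO library b (-0.30) or CRO library b (-0.37), and the miR-181 family without CRO library b (-0.43). In the authors' table the medians were 0.19 for the list induced on T cell activation, 0.20 for the miR-17-92 cluster and its paralogues, -0.010 for the let-7 family, 0.057 for the miR-15/16 family and 0.17 for the miR-23/24/27 clusters. They were -0.20 for the miR-181 family, -0.0050 for the miR-30 family, 0.20 for the miR-29 family, 0.048 for the interferon and NF-kB list and 0.11 for the p53 list. They were -0.21 for the Dlk1-Dio3 cluster, -0.015 for endothelial and stromal markers, -0.11 for epithelial markers, 0.29 for muscle and neural markers and 0.19 for miR-142.

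**Figure D3:**
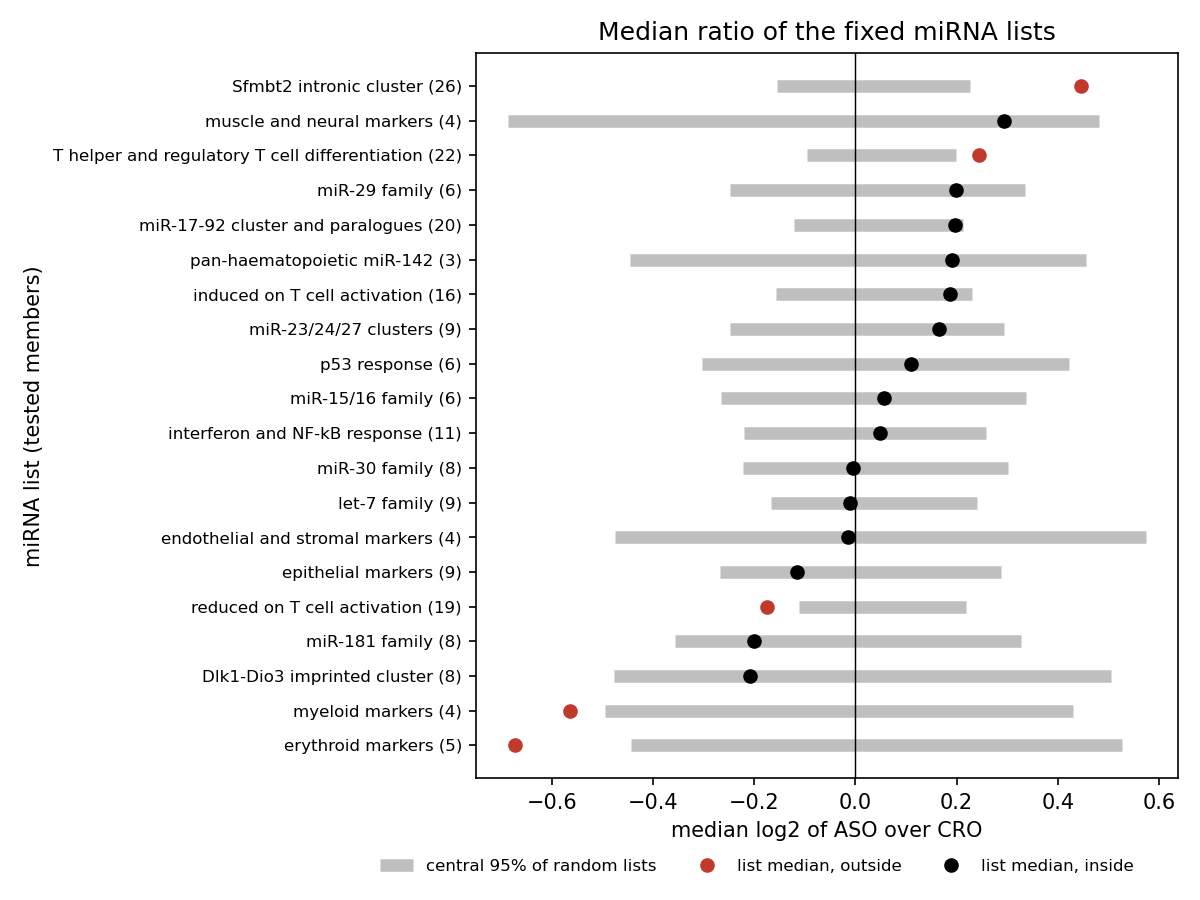
Median log2 ratio of ASO over CRO for each of the 20 lists, with the number of tested members in brackets and a grey bar for the central 95% of random lists matched on mean expression. The 5 red medians lie outside their bars, from -0.67 for erythroid markers to 0.45 for the Sfmbt2 cluster.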

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

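The design named limma-trend and camera at a correlation of 0.01 for deposited values per library. Their use on decoded libraries was added after the data were seen. The settings varied on that fit had been planned for deposited values. The main limits are 2 libraries per group, CRO libraries of only 5617699 and 3300457 counts, and calls that move when 1 library is left out. No paired analysis was possible because the group means carry no replicate number for the decoded libraries. edgeR and DESeq2, planned for deposited counts, were not run on the decoded counts. The count of miRNAs lower in ASO stayed within 1.5 times the main 12 under every alternative that kept all libraries, between 10 and 17. Leaving out 1 library at a time gave 4 to 32 lower and 0 to 31 higher, where a lone library is assumed to vary like the other group. Such a fit estimates variation only from the group that keeps both libraries. The median absolute log2 ratio between libraries was 0.23 in ASO and 0.39 in CRO, so these counts do not measure the effect of 1 library. Whether that accounts for the whole range of counts was not tested. The 1 higher miRNA became 4 with a raw p under 0.05 and at least a 2-fold difference. With a base mean of at least 50 it became 0, both in the authors' readjusted p and in limma (47 at an unadjusted p under 0.05), since miR-499-5p lies under that floor. The 21 miRNAs of the authors' own rule became 13 with an adjusted p under 0.05. Without the single most counted miRNA, the other 4 made up 44.0% in ASO and 42.0% in CRO. The 5 lists outside the random range became 2 with camera at a correlation of 0.01, 0 with an estimated correlation and 1 with fry, which test different questions, and 3 to 7 when 1 library was left out. They became 6 in the limma fits with the main and both other pseudocounts, both scalings and voom, where the miR-17-92 list was added. Over 369 alternative values of the named miRNAs, 326 kept their direction and side of the threshold. Of the rest, 10 no longer passed, 11 newly passed, 22 changed sign without passing in either, and 0 called values changed sign. For miRNAs whose groups do not overlap, among them all of the authors' calls, leaving out a library cannot turn the sign.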

Other observations

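Of the tests in this part, the search for ribosomal matches and the muscle miRNA test were set out before their results were seen, and the other 4 were chosen afterwards, those of a single library and of depth in place of earlier ones.

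miRNAs whose precursor matches a snoRNA or scaRNA transcript, small RNAs that guide the modification of other RNAs, were mostly lower in ASO: of 22 with a base mean of at least 10, 20 had a ratio below 0, against 44.8% of the others. Their median log2 ratio was -0.48, below the central 95% of matched random sets (-0.21 to 0.26), but that set holds the members that prompted the test and mostly pairs of arms from 13 precursors. Without the 6 members at a raw p under 0.05, the other 16 had a median of -0.22, beside a range of -0.23 to 0.28 for miRNAs that are likewise not past it, and 14 of the 16 lay below 0. That split is made on the change itself and all 6 removed were lower, so it does not decide whether those members alone carry the shift, and a chance choice of miRNAs stays open. For 7 of the 22 the matched transcript itself carries a miRNA name in the annotation, and no biological explanation was tested.

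For the 12 miRNAs lower in ASO, the difference was not confined to 1 library in these data. Whether a single library shaped the calls or their size could not be told. Their groups lay apart in 12 of 12 and their median stayed between -2.58 and -2.34 without each library in turn. The highest log2 ratio among them was -1.55 without ASO library a, -1.23 without ASO b, -1.38 without CRO a and -1.54 without CRO b. Calling them on the same 4 libraries largely fixes that the groups lay apart and favours the other results, so the size of the change stays uncertain. A further test took the wider set of miRNAs called lower without 1 library. The library left out gave medians of -2.79 (ASO library a), -2.40 (ASO b), -0.90 (CRO a) and -1.71 (CRO b). The median for CRO a met neither bound set for that test, so the test did not decide. A scaling difference moves all miRNAs alike, and the values argue against it for the 12. Their median log2 ratio was -2.48 with the decoded size factors, -2.535 with library totals and -2.39 with the upper quartile. The median of all 482 tested miRNAs was 0.041. Unscaled counts were fewer in the deeper ASO libraries for 12 of the 12. That only follows from scaled log2 ratios of -1.45 or lower and a median unscaled log2 ratio of 1.22 for all tested miRNAs. Depth goes with the groups, so any effect of depth beyond scaling stays open. Fragments of ribosomal RNA counted under miRNA names may still be a source. Of the 10 searched precursors, 0 matched a ribosomal transcript. miR-712-5p and miR-712-3p, described above as products of ribosomal RNA precursors, had no precursor sequence and were not searched. The search set also held 0 transcripts annotated as 28S, and the 28S gene of the reference table spans 420 bases. The prediction had counted at most 1 match as evidence against this source. That bound was set aside for the lack of 28S only after the 0 matches were seen. An effect of ASO itself remains untested.

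For miR-499-5p, reads of heart or skeletal muscle RNA could not be excluded by the criterion set beforehand. Exclusion needed fold differences of miR-1a-3p and miR-133a-3p. However, miR-133a-3p was not analysed here, and miR-1a-3p had 2 counts over both ASO libraries and 0 in CRO, under the floor of 3. The other part of the criterion asked whether most muscle miRNAs with a base mean of at least 1 were at least 4-fold higher in ASO. Only 1 reached that mean, miR-206-3p, and 0 were 4-fold higher. The same ASO libraries held 149 counts of miR-499-5p, and miR-206-3p, another muscle miRNA, had decoded counts of 7 and 4 in ASO and 4 and 4 in CRO, too few to give a direction.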
